A study of Yarrowia lipolytica with 6 samples.

How the data were processed

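Total RNA came from 3 wild type (CXAU/AI) and 3 snf1 deletion cultures of Yarrowia lipolytica. Per the labels' protocols, precultures of 48 h in a uracil-containing medium were diluted to an optical density of 0.05 and grown for 24 h at 30 °C with shaking at 220 rpm. Cells were washed, held for 1 h in medium with 2% n-decane and 1% uracil, and separated from the oil with 0.1% Triton-X. Libraries were made with a directional kit, per the labels. The submitters' processing notes name Trimmomatic 0.38.0, HISAT2 2.2.1, StringTie and DESeq2 2.11.40.7. The genome build, the counting options and the use of strand in counting are not given in the sources used here, so reads of a gene and of an antisense or overlapping transcript cannot be told apart.

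The authors deposited whole-number counts per feature for each library, with 9235 features in each. Per the file headers and identifiers, these are 6447 RefSeq protein-coding transcripts, 2087 transcripts assembled by StringTie, 510 RNA genes, 129 RefSeq non-coding transcripts and 62 mitochondrial genome features. Counts are per transcript, so reads that overlap several transcripts may have been split or left out by the authors. The authors also deposited a DESeq2 table of 2840 genes, all with adjusted p-values under 0.05. The deposited log2 fold changes were entered as a score because a stray value on a line with no gene ends the column. That line was left out, and the rest are read as log2 fold changes. For the closest pairs of the join described below, the deposited values lay a median of 0.06 from the shrunken ones of the counts. The residual SD, taken from the median absolute deviation, was 0.01. The join uses the fold change, so this closeness is partly built in. The deposited standard errors, means and p-values were used as given. These fold changes code the deletion over wild type, as the sign of Snf1 shows. The standard errors in the deposited table are those of the log2 fold changes, and the means are of normalised counts. Of its genes, 2109 have a protein-coding locus tag and 28 a name. The deposited start positions did not follow the order of the locus tags, so no coordinates are given.

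Totals ranged from 32315239 to 38054417 counts per library. Counting intervals and floors cover counting error only. No pair of libraries within a group agreed within sampling noise (chi-square per feature at least 306). Spearman correlations of log2 CPM were 0.942 to 0.977 within groups and 0.825 to 0.875 between them. The biological coefficient of variation was 0.363.

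Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The groups were compared with edgeR's quasi-likelihood test on all 6 libraries, with TMM scaling, filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), no covariates and Benjamini-Hochberg adjustment at 0.05. The standard error is the size of the log2 fold change divided by the square root of F. On simulated counts for the 7244 tested features, 5 of 67 changes of 1 on the log2 scale were recovered, 51 of 67 of 2 and 66 of 66 of 4, with 7 false calls. Few of the simulated 2-fold changes were thus recovered. The simulation changed far fewer features than were called in the counts, so the unadjusted p needed to pass was lower in it. These shares therefore do not measure the power of the comparison.

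Count rows carry RefSeq accessions and the deposited table carries locus tags and names, with no shared identifier. A gene was tied to the transcript on the same chromosome whose mean, shrunken log2 fold change and standard error, from DESeq2 with a fold-change prior, were nearest to the deposited ones. A tie needed to be mutual, with a scaled distance under 30, and the next transcript at 5 or more and at least 3 times as far. This join was designed after seeing the data. Of 2111 genes, 1198 were tied. The order along the chromosomes was not used, and 97.8% of tied genes with a position in the CLIB89(W29) assembly lay on the longest run in order, against 12.3% for shuffled positions. When the chromosome was wrong on purpose, 105.4 genes on average were still tied, against 1198 on the right chromosome, so some ties may be wrong. In 2000 simulated genes all 1642 ties were right. Each simulated gene was drawn from the transcripts themselves, so its true partner was always present. The simulation thus does not cover deposited genes that lack a true partner. Fold changes of tied genes match the deposited ones by construction. The reference table gave chromosomes and neighbours only. Of the 28 named genes, FAA1, ALK7 and Yas3 were not tied.

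Gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the deleted gene, and the 12 largest rises and 12 largest falls among features past the threshold with a mean of at least 10 CPM and no overlap between groups. It also names 2 to 4 members per list, by size of change among those past the threshold. All members are named for the ALK, alcohol and aldehyde, and beta-oxidation lists. Beyond the rule, the text names some members whose call depended on the setting or that had values only in the deposited table. The only rise of the glycerol list was also added. Of 141 listed tags in 13 lists, 92 were found in the deposited table, 2 of them by symbol because the row has no tag. The table names 23 listed tags, 20 with the symbol of the list and 3 with another symbol. The tag listed for ALK7 has a row of its own in the table, but the table gives that name to another tag. The listed tag was left out with its fold change, and the named row took its place. Other members are given by tag.

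The planned camera test of these lists was void, because tags are known only for genes that passed the authors' test. It was replaced, after seeing the data, by a one-sided hypergeometric test of presence in the deposited table (2109 tags, background 5613 tested coding transcripts) and a two-sided Fisher's exact test of direction against the other protein-coding tags (1231 lower and 878 higher in all), adjusted over the lists. Membership of the table is the authors' call on the same libraries, so counts adjusted over the list alone are no independent evidence. The hypergeometric and Fisher's tests treat genes as independent draws. Genes of a list can be regulated together, so these p-values may be too small. They do not measure variation between cultures. Keyword lists need an annotation text that was not used here, except for RNA genes, where camera (preset correlation 0.01) was run. Alternatives covered scaling, filter, test, replicate block, each library left out and a fold threshold, and their effect is given in the closing section. Protein-coding transcripts only, and library totals without the 100 most abundant features, were added after seeing the data.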

Results

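Transcript levels were measured by RNA sequencing in the oil yeast Yarrowia lipolytica, which can grow on alkanes. The parent strain CXAU/AI, called wild type here, was compared with a strain lacking SNF1, the gene of a protein kinase known in yeasts for its part in the use of carbon sources other than glucose. Each group had 3 libraries, which the labels describe as biological replicates. Cells had been grown for 24 h at 30 °C and then held for 1 h in medium with 2% n-decane, an alkane, and 1% uracil. Total counts ranged from 33835106 to 38054417 in wild type and from 32315239 to 37094343 in the deletion. Levels below are CPM (counts scaled to a fixed library total) after TMM scaling, as mean ± SD with n = 3 libraries per group. Fold changes and adjusted p-values come from edgeR's quasi-likelihood test unless the authors' deposited table, a DESeq2 comparison of the same strains, is named.

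The deleted gene was read first, as a check of the labels. SNF1 (listed as Snf1, YALI0_D02101g) stood at 101 ± 23.1 CPM in wild type, with 2546 to 3644 counts per library. All 3 deletion libraries held 0 counts, which made it at least 1326-fold lower against a floor of 3 counts per library (adjusted p = 3.26e-07). No library went against its label.

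The question of the comparison was which transcripts differ after 1 h with decane when Snf1 is missing. All libraries came from cells held with decane, so whether a difference was there before decane cannot be told. Among genes for the use of alkanes and fatty acids, POX4 changed by -9.46 on the log2 scale, FALDH1 by -9.92 and ALK5 by -8.48. The authors' deposited table gives names to 28 genes, Snf1 among them, and all 28 are listed there as lower. Of these, 25 could be tied to a row of the counts, and all 25 fell in the edgeR test. That table holds only genes past the authors' test on the same libraries, and a tie needs a like fold change, so these falls are no independent evidence of direction. The 24 tied genes other than Snf1 together held 7.81 ± 1.12% of all counts in wild type and 0.300 ± 0.0817% in the deletion.

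**Figure D1:**
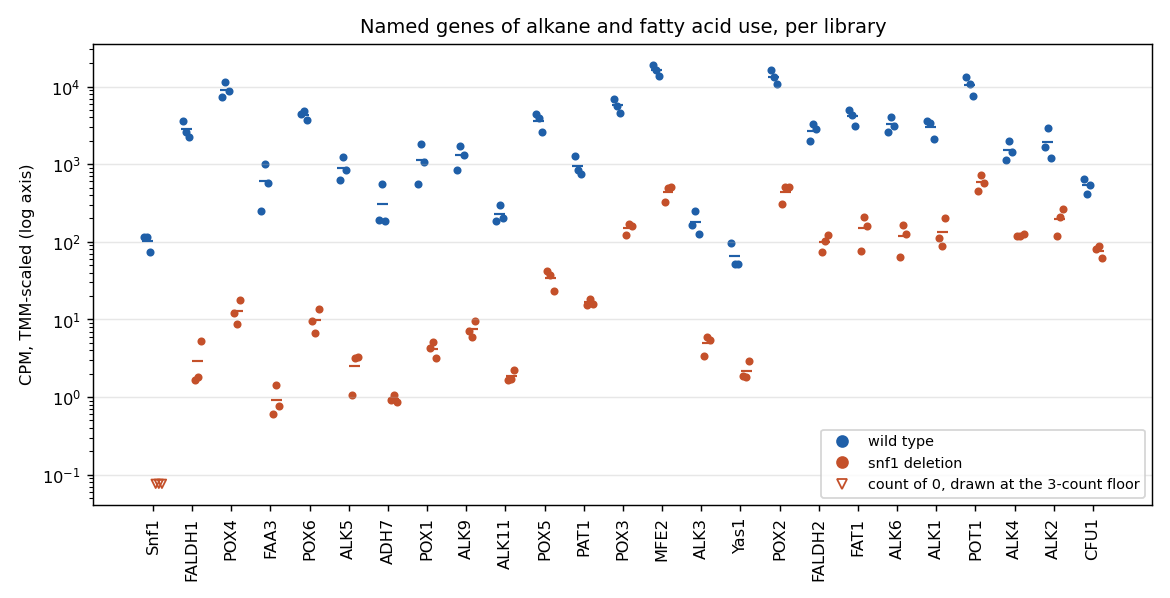
Level of each named gene in each library, in TMM-scaled CPM on a log axis, with blue points for the 3 wild type libraries, orange points for the 3 deletion libraries and short lines for the means. All 25 genes lie lower in the deletion, and the open triangles mark the 0 counts of Snf1 at the floor of 3 counts.

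The ALK genes encode cytochrome P450 enzymes that add oxygen to alkanes, the opening step of their breakdown. Of the 12 listed members, 9 are lower in the authors' deposited table and 3 are not in it. The 8 tied to counts all fell, also when adjusted over the list alone. ALK5 fell from 899 ± 303 CPM to 2.51 ± 1.25 CPM (log2 fold change -8.48, SE 0.62, adjusted p = 1.01e-06). ALK9 fell from 1302 ± 448 CPM to 7.5 ± 1.83 CPM, and ALK11 from 226.5 ± 59.1 CPM to 1.87 ± 0.331 CPM. ALK3 changed by -5.20 on the log2 scale, ALK6 by -4.77, ALK1 by -4.50, ALK4 by -3.66 and ALK2 by -3.31. ALK6, with the highest mean of them in wild type, stood at 3245 ± 744 CPM there and at 119 ± 51.5 CPM in the deletion. ALK1 was close to it in wild type, at 3042 ± 818 CPM. ALK7 is listed at -1.17 in the authors' deposited table (adjusted p = 0.0069) and was not tied to a count row. More members were in that table than its share of protein-coding tags would give (hypergeometric test, adjusted p = 0.0207), while the Fisher's exact test of their direction missed the threshold (adjusted p = 0.0512). Here and for the lists below, these tests count genes as independent and do not cover variation between cultures.

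Enzymes that oxidise fatty alcohols and aldehydes form the next list, with 9 of 13 members lower, 2 higher and 2 absent in the authors' deposited table. Of the 10 tied to counts, 8 fell, 1 rose and 1 did not pass. When adjusted over the list alone, 8 fell and 2 rose. The aldehyde dehydrogenase gene FALDH1 fell from 2818 ± 687 CPM to 2.92 ± 2.03 CPM (log2 fold change -9.92, SE 0.71, adjusted p = 9.75e-07), and its log2 fold change was -10.65 without deletion replicate 3. FALDH2 fell from 2704 ± 633 CPM to 99.9 ± 23.4 CPM. The alcohol dehydrogenase gene ADH7 fell from 309 ± 212 CPM to 0.953 ± 0.111 CPM, a log2 fold change of -8.33, or -7.59 without wild type replicate 2. Members known here by locus tag fell as well, with log2 fold changes of -7.77 for YALI0_D25630g (-6.88 without wild type replicate 2), -6.89 for YALI0_A16379g, -4.67 for YALI0_A15147g, -4.62 for YALI0_E17787g and -2.32 for YALI0_B14014g. YALI0_E15818g is listed at -6.16 in the authors' deposited table. YALI0_F09603g rose from 86.4 ± 14.1 CPM to 177 ± 22.7 CPM (log2 fold change 1.04, SE 0.31, adjusted p = 0.019), a call that was lost without wild type replicate 3 (adjusted p = 0.071), deletion replicate 1 (0.0551) or deletion replicate 3 (0.0598). YALI0_D02167g had a log2 fold change of 0.83 (SE 0.36, adjusted p = 0.0823) and passed without wild type replicate 2 (adjusted p = 0.037), with library size only (0.013) and with upper-quartile scaling (0.0123). Presence of the list in the table passed (adjusted p = 0.00341) and its direction did not (adjusted p = 0.194).

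Peroxisomal beta-oxidation, which shortens fatty acids, was lower throughout: all 14 members of the list, including fatty acid activation, are lower in the authors' deposited table. The 11 tied to counts all fell, also when adjusted over the list alone. The acyl-CoA oxidase genes ranged from -9.46 for POX4 to -4.93 for POX2, with POX6 at -8.77, POX1 at -8.09, POX5 at -6.73 and POX3 at -5.24. POX4 went from 9146 ± 2147 CPM to 12.9 ± 4.65 CPM (SE of the log2 fold change 0.65, adjusted p = 9.29e-07). The multifunctional enzyme gene MFE2 stood at 16331 ± 2762 CPM in wild type and at 442 ± 102 CPM in the deletion. The thiolase gene POT1 went from 10598 ± 2870 CPM to 588 ± 139 CPM. PAT1 changed by -5.85 on the log2 scale, FAT1 by -4.79 and YALI0_D04246g by -2.87. Not tied to counts, YALI0_E03058g, YALI0_A06655g and FAA1 are at -4.35, -2.12 and -1.91 in the authors' deposited table. Both the presence of the list (adjusted p = 0.000345) and its direction (adjusted p = 0.012) passed.

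Peroxisome biogenesis genes moved the same way. Of 15 listed tags, 12 are lower in the authors' deposited table and 3 are absent. The 11 tied to counts all fell, also when adjusted over the list alone. YALI0_C04092g fell from 2948 ± 889 CPM to 82.6 ± 25.2 CPM, a log2 fold change of -5.16 (SE 0.50, adjusted p = 6.73e-06). YALI0_E06831g changed by -4.14, YALI0_C18689g by -3.67 and YALI0_F01012g by -3.45. Presence (adjusted p = 0.00341) and direction (adjusted p = 0.012) both passed.

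Among 6 listed regulators and transporters of alkane and oleate use, 5 are lower in the authors' deposited table and 1 is absent. Yas1, a transcription factor that activates alkane-responsive genes, fell from 66.3 ± 25.6 CPM to 2.19 ± 0.635 CPM (log2 fold change -4.92, SE 0.40, adjusted p = 1.83e-06). YALI0_E14729g fell from 159 ± 43.2 CPM to 6.41 ± 1.74 CPM. Both fell when adjusted over the list alone. Yas3, known as a repressor of those genes, is at -0.94 in the authors' deposited table (adjusted p = 0.012), where YALI0_E32417g is at -2.71 and YALI0_E07942g at -1.24. Neither presence (adjusted p = 0.239) nor direction (adjusted p = 0.194) of the list passed. Outside this list, FAA3 fell from 605 ± 376 CPM to 0.927 ± 0.428 CPM. Of the 3 tags listed for the kinase complex and its upstream kinase, only SNF1 itself is in the table.

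**Figure D2:**
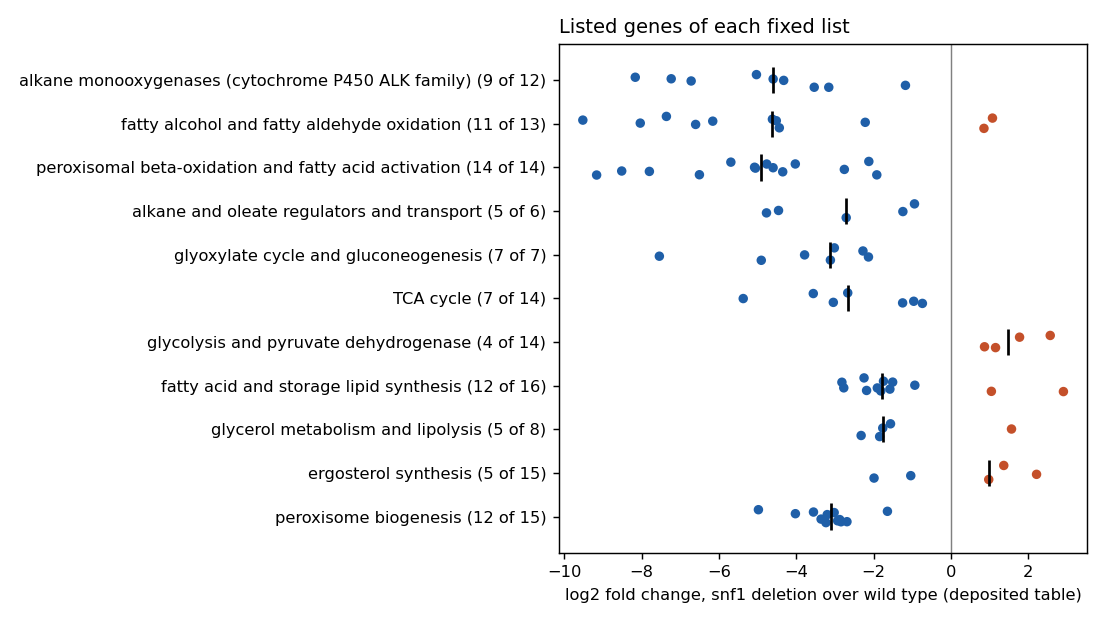
Log2 fold change of the deletion over wild type, from the authors' deposited table, for the members of each fixed list that the table holds, with a black line at each list's median and the number of members held out of those listed. All 14 members of the beta-oxidation list and all 12 held members of the peroxisome list lie below 0, whereas the 4 held glycolysis members lie above it.

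The glyoxylate cycle and gluconeogenesis build sugars from the acetyl-CoA that beta-oxidation releases. All 7 listed tags are lower in the authors' deposited table, and all 7 fell in the counts, also when adjusted over the list alone. YALI0_C16995g fell from 2693 ± 1274 CPM to 12.3 ± 2.98 CPM (log2 fold change -7.77, SE 0.58, adjusted p = 1.07e-06). YALI0_E15708g changed by -5.03, YALI0_F31999g by -3.93 and YALI0_F05962g by -3.23. Presence passed (adjusted p = 0.00341) and direction did not (adjusted p = 0.0923). In the TCA cycle list, 7 of 14 tags are lower in that table and 7 are absent. Of the 6 tied to counts, 5 fell, and 6 when adjusted over the list alone. The weakest of the 5, YALI0_E33517g (adjusted p = 0.0409), did not pass without wild type replicates 2 or 3 (adjusted p = 0.0871 and 0.0886) or deletion replicates 1 or 3 (0.16 and 0.141), nor with library size only (0.192) or upper-quartile scaling (0.164). YALI0_D23397g (adjusted p = 0.0143) did not pass without deletion replicate 1 (0.0652), with library size only (0.0603) or with upper-quartile scaling (0.0505). YALI0_E00638g fell from 3454 ± 1350 CPM to 73.4 ± 15.1 CPM, and YALI0_E02684g changed by -3.15. Neither test of the TCA list passed (adjusted p = 0.352 for presence and 0.0923 for direction).

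Of 14 tags for glycolysis and pyruvate dehydrogenase, 4 are higher in the authors' deposited table, none is lower and 10 are absent. Of the 3 tied to counts, 2 rose, and 3 when adjusted over the list alone. YALI0_F16819g rose from 339 ± 129 CPM to 1158 ± 209 CPM (log2 fold change 1.77, SE 0.41, adjusted p = 0.00434). YALI0_F20702g rose from 232.5 ± 71.4 CPM to 511 ± 4.58 CPM (adjusted p = 0.0231), but did not pass without wild type replicate 1 (adjusted p = 0.0559), wild type replicate 3 (0.0961) or deletion replicate 3 (0.0867). The member that did not pass, YALI0_F05214g (log2 fold change 0.86, adjusted p = 0.0677), passed without deletion replicate 2 (adjusted p = 0.0445), with library size only (0.0145) and with upper-quartile scaling (0.0132). YALI0_F09185g is at 2.57 in the authors' deposited table. Neither the presence of the list (adjusted p = 0.904) nor its direction (adjusted p = 0.0898) passed.

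Synthesis of fatty acids and storage lipids was mixed. Of 16 tags, 10 are lower, 2 are higher and 4 are absent in the authors' deposited table. Of the 11 tied to counts, 8 fell and 2 rose, with 9 and 2 when adjusted over the list alone. The weaker of the 2 rises, YALI0_B19382g (adjusted p = 0.0484), did not pass without wild type replicate 1 (adjusted p = 0.13), wild type replicate 3 (0.182), deletion replicate 1 (0.164) or deletion replicate 3 (0.0808), or with DESeq2 size factors (0.06). Of the falls, YALI0_F06754g rested on wild type replicate 2, without which its log2 fold change went from -2.02 to -0.87 (adjusted p = 0.103). YALI0_E32769g fell from 405 ± 60.2 CPM to 52.9 ± 16.7 CPM (log2 fold change -2.94, SE 0.37, adjusted p = 6.32e-05), and YALI0_E16797g changed by -2.87. YALI0_D24431g rose to 905 ± 160 CPM (log2 fold change 2.93, SE 0.41, adjusted p = 0.000147). Presence passed (adjusted p = 0.0068) and direction did not (adjusted p = 0.194). Of 8 tags for glycerol metabolism and lipolysis, 4 are lower, 1 is higher and 3 are absent in that table, and all 5 passed in the counts, also when adjusted over the list alone. YALI0_F00484g (log2 fold change -1.66, adjusted p = 0.0247) was lost without wild type replicate 1 (-0.66, adjusted p = 0.148), without deletion replicate 3 (adjusted p = 0.079), with library size only (0.051) and with upper-quartile scaling (0.0521). YALI0_D17534g changed by -2.41 and YALI0_B13970g by 1.55. Of 15 ergosterol synthesis tags, 2 are lower, 3 are higher and 10 are absent. Of its 4 tied to counts, 2 fell and 1 rose, with 2 each way when adjusted over the list alone. The weaker of the 2 falls, YALI0_B23298g (adjusted p = 0.0216), passed in only 1 of the 6 fits that left out a library. Its adjusted p was 0.0923 without wild type replicate 2, 0.0643 without wild type replicate 3, and 0.0521, 0.0508 and 0.0671 without deletion replicates 1, 2 and 3, and it was lost with library size only (0.0991) and upper-quartile scaling (0.0943). The member that did not pass, YALI0_F11297g (log2 fold change 0.96, adjusted p = 0.0502), passed without wild type replicate 2 (adjusted p = 0.00713) or deletion replicate 2 (0.0472), with library size only (0.00589) and with upper-quartile scaling (0.0065). YALI0_F11297g also passed in limma-voom (adjusted p = 0.033), with the replicate block (0.0412) and with at least 1 CPM in 3 libraries (0.043). It did not pass with DESeq2 size factors, in the DESeq2 test, under glmTreat or with no low-count filter. YALI0_F08701g changed by -2.07 and YALI0_F30481g by 2.25. Neither of these 2 lists passed a test (glycerol adjusted p = 0.239 and 0.491, ergosterol adjusted p = 0.894 and 0.714, for presence and direction). None of the 4 auxotrophic marker tags is in the table.

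Over all features, 7244 of 9235 had enough counts to be tested. Of these, 1329 were higher and 1356 lower in the deletion at adjusted p under 0.05, of which 1242 and 1238 had an estimated change of at least 2-fold. Tested against a 2-fold change itself (glmTreat), 505 were higher and 641 lower. Large falls outnumbered large rises, with 142 features lower and 62 higher by at least 16-fold. The groups did not overlap for 3580 features, or 49.4%, where chance gives 10%. The split between higher and lower depended on the scaling: 67.5% of calls were higher with library size only or with upper-quartile scaling, against 49.5% with TMM. These 2 settings shifted the median log2 fold change of all features by 0.36 and 0.35. Without deletion replicate 3, 873 features were higher and 951 lower.

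The 12 largest falls include 8 genes named above: Snf1, FALDH1, POX4, FAA3, POX6, ALK5, ADH7 and POX1. The others were YALI0_F27005g, YALI0_D00176g, YALI0_E05951g and the StringTie transcript MSTRG.2429.1. YALI0_F27005g fell from 5503 ± 2337 CPM to 3.35 ± 0.844 CPM (log2 fold change -10.68, SE 0.69, adjusted p = 9.29e-07). YALI0_D00176g, at 9795 ± 2113 CPM in wild type, stood at 32.2 ± 11.5 CPM in the deletion. YALI0_E05951g changed by -8.17 and MSTRG.2429.1 by -7.92, or by -8.70 without deletion replicate 3.

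None of the 12 largest rises carries a gene name in the files. MSTRG.5601.1 had 2 counts in all of wild type, both in replicate 3, and 2548 in the deletion, a ratio of 1033 with a 95% counting interval from 285.6 to 8531. YALI0_D04356g rose from 1.98 ± 0.303 CPM to 469.9 ± 92.0 CPM (log2 fold change 7.89, SE 0.45, adjusted p = 3.26e-07). YALI0_B04202g rose to 1248 ± 193 CPM (log2 fold change 6.59), and YALI0_D02453g from 5.47 ± 1.21 CPM to 761 ± 255 CPM. YALI0_A19228g changed by 7.44, YALI0_F25993g by 7.37, YALI0_B20328g by 6.23 and YALI0_B23452g by 5.78, or by 5.11 without deletion replicate 2. Rises of 5.44, 5.36, 5.05 and 4.99 were found for rna-XM_002143031.1, YALI0_E10219g, MSTRG.5442.1 and YALI0_B07898g.

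**Figure D3:**
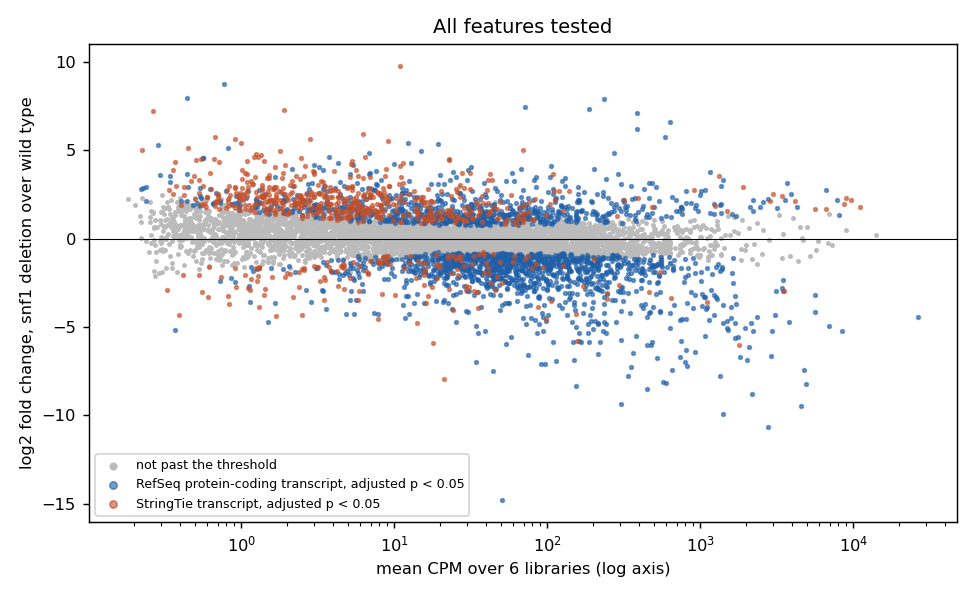
Log2 fold change of the deletion over wild type against mean CPM over the 6 libraries (log axis) for the 7244 features tested, with RefSeq coding transcripts past the threshold in blue, StringTie transcripts past it in orange and features not past it in grey. The largest falls lie among abundant RefSeq coding transcripts, and the point near the bottom is Snf1 at its fitted value, which is no measure of the fold because the deletion libraries held 0 counts.

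RNA genes with locus tags ending in r, the list for tRNA and rRNA, were the only keyword list that the identifiers allowed. Of 21 tested, 3 rose (YALI0_C11737r, YALI0_A13343r and YALI0_E22308r) and 3 fell (YALI0_D09405r, YALI0_C02277r and YALI0_C14080r), names that were added after their values were seen. Wild type levels of these genes were low, from 0.111 ± 0.0966 CPM for YALI0_A13343r to 11.9 ± 5.83 CPM for YALI0_D09405r. As a set they did not pass (limma's camera p = 0.266, and p = 0.497 with an estimated correlation). The filter let more RNA genes in when a library was left out, and the larger set then passed in 4 cases. Camera in limma gave p = 0.0269 (n = 34 genes) without wild type replicate 1, p = 0.027 (n = 34 genes) without wild type replicate 2, p = 0.00812 (n = 32 genes) without wild type replicate 3 and p = 0.0304 (n = 27 genes) without deletion replicate 1.

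Where a StringTie gene has a single counted transcript, it can be compared with the authors' deposited table by its identifier. Of 630 such transcripts, 612 (97.1%, Wilson 95% interval 95.5 to 98.2%) had the same sign in both, and 554 of the 557 that passed in edgeR did. Both signs come from the same libraries, and the table holds only genes past the authors' test, so this is no independent evidence. The interval treats transcripts as independent and does not cover variation between cultures. The table holds 1381 higher and 1459 lower genes in all. Tags of genes outside that table are not tied to count rows here, so a listed gene that is absent from it was not measured as unchanged, and some rows of the table carry no tag. The POX and ALK families have related sequences, and how reads with several matches were counted is not given in the sources used here.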

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

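Protein-coding transcripts only, library totals without the 100 most abundant features, and the split of simulated changes by level were chosen after seeing the data. The main counts were 1329 features higher and 1356 lower. Upper-quartile scaling gave 2005 higher, glmTreat against a log2 fold change of 1 gave 505 higher and 641 lower through its stricter null, and totals without the 100 most abundant features gave 2148 higher and 877 lower. Library size only gave 1946 and 936, and protein-coding transcripts only gave 967 and 1065. Whether a few abundant features brought about the larger share of higher calls was tested against a bound set before its result was seen. Without the 100 most abundant features 71.0% of calls were higher, against 49.5% with TMM. The share did not return to within 10 points, so this explanation failed for that set of features. Of the 50 most abundant over all 6 libraries, 17 were higher and 15 lower. Leaving out only abundant features that fell was not tested, so their part stays open. No other cause of the scaling differences was tested. Leaving out 1 library gave 873 to 1351 higher and 951 to 1366 lower, with fewer samples, and both lowest values came without deletion replicate 3. No called feature changed sign under any of these settings. SNF1 kept its direction and its side of the threshold throughout. The 67 tied list members that fell were 59 to 69 under the alternatives. The 7 that rose were 10 with library size only, with upper-quartile scaling and with totals without the 100 most abundant features, 2 under glmTreat and 4 to 9 with 1 library left out, 4 without wild type replicate 3 and 4 without deletion replicate 3. The sign agreement with the deposited table was 95.6 to 97.5%. For the RNA genes, limma's camera gave p = 0.266 (n = 21 genes), and p = 0.00523 with no low-count filter, where the set held many more genes (n = 313 genes). Leaving out a library gave p = 0.00812 to 0.236 on sets from n = 27 to n = 34 genes, so these are other sets, and whether their added weak genes brought the change was not tested. Camera on the tag lists was not run because it was void. Over 95 named features no direction was reversed, and 51 values lost and 21 gained their call over all alternatives. Leaving out 1 library moved the fold change of 8 of the 95 by over 1.5 times. YALI0_B19382g, YALI0_E33517g and YALI0_B23298g lost it most often. The replicate block, where the numbers are not known to pair the cultures, gave 1412 higher and 1342 lower. Same-numbered libraries deviated together with correlations of 0.0507, 0.146 and 0.141. Set against the libraries of the other group only, 5 of 6 libraries correlated best with the one of their own number. Spearman correlations within groups (0.942 or more) all exceeded those between groups (0.875 or less). Of simulated changes of 2 on the log2 scale, 18 of 29 were recovered in features at or below the median level of 26.5 CPM and 33 of 38 above it. For changes of 1 these were 1 of 35 and 4 of 32, so few simulated 2-fold changes were recovered at either level.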

Other observations

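The tests of library scaling, of reads moving between transcripts and of the neighbours of SNF1, and the mitochondrial set, were chosen after the results were seen. The test of background reads was redefined after its earlier form gave 0 in every library. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 2685 features and the highest of the other splits called 0, so that 1 split reached the real count. Every other split put both genotypes on each side, so a difference between genotypes itself widens the spread within its groups. No conclusion is drawn from the contrast with 0.

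Transcripts that StringTie assembled beyond the annotation took 7.68 ± 1.83% of counts in wild type and 19.3 ± 4.04% in the deletion (n = 3 each, exact permutation p = 0.1, the smallest possible). Of 1578 tested, 522 were higher and 157 lower, whereas of 5613 RefSeq coding transcripts 797 were higher and 1196 lower. In a refit on coding transcripts alone, 967 of them were higher and 1065 lower, so the excess of falls in this class was smaller. Library sizes, scaling, dispersions and adjustment all changed together in that refit. RefSeq non-coding transcripts had 7 of 22 higher and none lower. Transcripts of the mitochondrial genome did not pass: of 10 tested, edgeR called 0 (0 at unadjusted p under 0.05), limma-voom 0, and DESeq2 0 of 27 (1 at unadjusted p under 0.05). Among the 50 most abundant features over all 6 libraries, 17 were higher and 15 lower. Among the 50 most abundant in wild type, a choice that favours falls, 29 were lower and 4 higher.

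The split between the 2 transcript classes, with 76.9% of StringTie calls higher, 36.9 percentage points above RefSeq coding calls, was weighed against 3 technical explanations. For scaling of the libraries, the smallest gap over 4 scalings was 25.8 percentage points, so the choice among these 4 did not close it. Each of them scales all features of a library alike and so moves both classes in the same direction. A scaling that treats the classes separately was not part of this test, so no wider conclusion on scaling is drawn. Reads moving between overlapping transcripts of one gene stay open: 82.6% of the 522 StringTie transcripts called higher belong to a gene that is higher in the authors' deposited table, but 489 of the 522 are their gene's only counted StringTie transcript, so both values can rest on the same counts. Abundance cannot be told apart from class: within 10 bins of mean CPM the gap averaged 21.5 points (SD 17.9), or 13.4 when bins were weighted by their StringTie transcripts, and an effect of the deletion itself stays open, untested. The mean exceeded the bound of 10 points set beforehand, which alone would have counted against abundance, but a further requirement, that it exceed the bound by the SD between bins, was added after the mean was seen.

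Weak RefSeq coding transcripts were mostly higher in the deletion. In the lowest abundance bin of called features 82.1% of them were higher, against 28.6% in the highest. Background reads spread over the genome, for example from residual DNA, may raise weak features, and would lift the low end of all coding transcripts. The 10th percentile was 1.27 ± 0.315 CPM in wild type and 1.78 ± 0.187 CPM in the deletion, a ratio of 1.41, but the groups overlapped (1.57 CPM in wild type replicate 1 and in deletion replicate 1). Background and a true rise of weak genes cannot be told apart from this value, since both predict it.

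Log2 fold changes of neighbouring genes, in the gene order of the CLIB89(W29) assembly, were weakly alike. Across 3751 pairs of adjacent genes Spearman's rho was 0.115 (permutation p = 0.000999, the smallest possible, adjusted p = 0.0025 over 5 distances). Genes are not independent replicates. If reads shared between adjacent genes were the whole cause, genes 2 apart would not be alike, but their rho was 0.057, above the upper permutation limit of 0.0318. At 3 genes apart rho was 0.00704 (permutation p = 0.349), and at 10 apart 0.0388 (permutation p = 0.00699). No biological explanation was tested.

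A further hypothesis was that the deletion altered its neighbours on the chromosome. Of the 3 genes on each side of SNF1, 1 passed, YALI1_D02348g, directly next to it, with a log2 fold change of -1.32 (adjusted p = 0.00714). The other 2 on that side had log2 fold changes of -0.87 (YALI1_D02345g, adjusted p = 0.053) and 0.66 (YALI1_D02316g, adjusted p = 0.167). The 3 on the other side had log2 fold changes of 0.73, 0.96 and 0.83, none past the threshold, and the last of them is YALI0_D02167g of the alcohol dehydrogenase list. The median size of the 6 changes was 0.85, and 33.5% of windows of 6 genes elsewhere reached as much. A median over 6 genes dilutes an effect on the adjacent ones, so the hypothesis stays open.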
